A study of Mus musculus with 14 samples.

How the data were processed

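Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was applied by the authors to basal keratinocytes sorted from the back skin of newborn mice. The labels describe 14 samples in 7 groups of 2 replicates: Ring1b, H2AK119ub, H3K27me3, H3K27ac, H3K4me1, H3K4me3 and input chromatin. Peak lists were read for 6 samples, the replicates of Ring1b, H2AK119ub and H3K27me3. The other 8 samples were not analysed here. Each of these 3 antibodies had 3 lists, 1 per replicate and a union, which gave 9 lists. Each sample's group and replicate number came from its title. The labels do not say that replicates came from separate animals or litters, so error between replicates measures only the spread between these samples.

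The submitters' processing notes name Trim Galore 0.4.1, Bowtie 1.1.1, Bowtie2 2.2.3, SAMtools 0.1.19 and MACS2 2.1.0, and the mouse build mm10. Which of these made the lists is not given in the sources used here, and the columns are not those that MACS2 writes. Per the file headers, each deposited row holds a peak's chromosome, start and end, its maximum height (a coverage signal), the counts of ChIP and input reads on each strand inside the peak, a p-value, a location class and the names of nearby genes. The read counts in the authors' lists were whole numbers, and no normalization of them is described. The height was used only to scale coverage in the test for chromosome X and to rank Ring1b regions in the test of weak signal. The test behind the deposited p-value, any scaling of the input and whether coordinates count from 0 or 1 are not given in the sources used here, so coordinates are printed as the lists give them and treated as closed intervals. Peaks had been called per replicate. A row by row comparison showed that each union list held every replicate 1 peak plus the replicate 2 peaks that overlapped none of them, so it was not a call on pooled reads. Its values per peak are the authors' own.

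Library totals are not given in the sources used here, and the reads counted inside peaks are not the depth of a library, because they rise with the length that was called. Median ChIP reads per peak were 68 and 63 in Ring1b replicates 1 and 2, 60 and 109 for H2AK119ub, and 434 and 418.5 for H3K27me3. The shortest peaks were 500 bp for Ring1b and H2AK119ub and 2003 bp (replicate 1) and 2006 bp (replicate 2) for H3K27me3. The share of peaks with a deposited p-value above 0.05 was 34.6% and 20.5% for the Ring1b replicates, 7.05% and 25.4% for H2AK119ub, and 2.04% and 0.0320% for H3K27me3. The fold used to describe and rank peaks was the ratio of the deposited ChIP read count to the deposited input read count in the same peak. It was compared only within the lists of a single antibody, and it was not scaled for library size.

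Peaks of both replicates of an antibody were merged where they shared at least 1 bp, and regions to which both replicates contributed were kept. A region or gene was called without a mark only where neither replicate list of that mark held a peak there. Those with a peak in 1 replicate were counted apart. A protein-coding gene carried a mark where both replicate lists named it in a row whose location class was promoter. Of 7264 gene names in the lists, 7074 matched a current symbol of the RefSeq table for GRCm38.p6 (the assembly behind mm10), 177 matched through a synonym and 13 did not match. The background was 21631 protein-coding genes on the 19 autosomes and chromosome X. Exons and introns were not told apart, since the table gave gene spans only. CpG content was not computed, since the genome sequence was not used here.

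Overlap between antibodies was tested by shifting the regions of the first antibody circularly along each chromosome 1000 times (seed 20), with a two-sided permutation p and Benjamini-Hochberg adjustment over 6 ordered pairs. Shares carry 95% Wilson intervals, which cover counting error only. Each of 18 gene lists was tested by two-sided Fisher's exact tests in 5 classes (Ring1b, H2AK119ub, H3K27me3, all 3, and Ring1b with neither mark), adjusted over the 90 tests together. Lists with at least 6 members that differed between a pair of marks were compared by exact two-sided McNemar tests, adjusted over 13 tests. Medians of the log2 Ring1b ratio were compared by a two-sided permutation test with 100000 resamples (10000 for alternatives). Promoter location was tested against the same shifts within 2000 bp of either end of a protein-coding gene, since strand was not given. Genes and regions are not independent replicates, so these tests describe the lists and not variation between animals.

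The samples, tests, gene lists, alternatives other than those said to be added later, and the rule for named genes were fixed before the data were examined. That rule took, from each of 3 classes (Ring1b with both marks, Ring1b with neither mark, both marks without Ring1b), the 10 genes with the highest rank of the ratio averaged over the replicate lists, up to 4 members of each list by the same rank, and 14 key epidermal genes whatever their call. Other genes named as examples of a count were chosen after their values were seen. Values of a few genes that entered the counts are not reported here. The plan departed in several ways once the columns were known. Promoters came from the authors' location class in place of 2000 bp around annotated starts. The ratio of read counts took the place of a caller's fold enrichment. The planned test of CpG-rich promoters, windows of 1000 and 5000 bp, the most upstream start and a threshold of 10 on the −log10 q scale were not run.

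Alternatives were the authors' union lists, an overlap covering at least 50% of the first region, regions within 1000 bp counted as shared, promoter regions alone, autosomes alone, leaving out each replicate, and same-numbered replicates compared with each other. Where a replicate was left out, its peaks no longer counted against a call of absence. Deposited p-value limits of 0.001 and 0.05, peaks of any location class and gene spans padded by 2000 bp were added after the data had been seen. Whether equal replicate numbers link libraries was checked by comparing same-numbered with crossed lists. The labels do not say that they do, and no such link was used in the main tests.

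Functions were tested on simulated data with known answers. The interval code gave the right answer for 300 of 300 simulated intervals. A planted overlap of 50% among 2500 regions was recovered as 50.5%, and 4 of 100 unrelated sets gave p under 0.05. These sets were placed at random over the chromosomes, unlike the real regions, which lay mostly at promoters. The simulated rate of false calls therefore does not carry over to lists that share such a placement. With 21000 simulated genes and an odds ratio of 8, 999 of 1000 enriched lists were called, as were 15 of 1000 lists with no enrichment. A step of 0.3 in the log2 ratio was called in 100 of 100 sets and a step of 0 in 6 of 100. The McNemar test called 911 of 1000 lists with a difference and 16 of 1000 without, at an unadjusted p under 0.05. These simulated lists had a nearly one-sided split and more differing genes than most of the real lists compared. The simulated rate of detection therefore does not carry over to the real, adjusted tests. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.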

Results

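The series asked where Polycomb repressive complex 1 (PRC1) acts in the progenitor cells of the skin epithelium. Basal cells of the epidermis were sorted from newborn mice (postnatal day 0) as Sca1-positive cells with a strong red reporter of Krt14, a keratin of the basal layer, and no green reporter of Krt10, a keratin of the layers above it. Chromatin from 6000000 cells was precipitated for Ring1b, the ubiquitin ligase subunit of PRC1, and from 400000 cells for H2AK119ub, the histone mark that PRC1 writes, and for H3K27me3, the mark written by Polycomb repressive complex 2. Each antibody had 2 replicates. H3K27ac, H3K4me1, H3K4me3 and input libraries were not analysed here.

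Ring1b peaks numbered 4452 in replicate 1 and 3058 in replicate 2, and covered 12.0 Mb and 8.76 Mb. H2AK119ub gave 3800 and 5712 peaks over 10.5 Mb and 23.3 Mb, and H3K27me3 gave 6040 and 3124 peaks over 41.8 Mb and 20.5 Mb. The reads inside these peaks were 1093268 and 786331 for Ring1b, 444944 and 1081890 for H2AK119ub, and 5212387 and 2367561 for H3K27me3. Replicates differed in how far each list reached. Of the Ring1b peaks of replicate 1, 56.8% were found in replicate 2, and 85.3% the other way round. For H2AK119ub these shares were 81.9% and 44.3%, and for H3K27me3 48.2% and 99.6%. Across shared regions the log2 ratio of ChIP to input reads correlated between replicates with Spearman's rho of 0.762 for Ring1b, 0.458 for H2AK119ub and 0.693 for H3K27me3 (Pearson's r 0.820, 0.424 and 0.698), over regions, which are not independent replicates. Regions found in both replicates numbered 2506 for Ring1b, 2473 for H2AK119ub and 2886 for H3K27me3, with median lengths of 2279.5 bp, 4797 bp and 7219 bp, and the comparisons below rest on them.

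The first comparison asked how far Ring1b and the histone marks of both Polycomb complexes occupied the same regions. The longest Ring1b region covered Hoxc8 to Hoxc13 (chromosome 15, 102894900 to 102999128, mm10, 104229 bp), and the next longest lay over the Hoxa and Hoxd clusters, whose genes set position along the body axis. A further Ring1b region of 65691 bp covered Zic1 and Zic4, zinc finger genes of the cerebellum and spinal cord (chromosome 9, 91346770 to 91412460, mm10). Long regions of both marks lay over the same 4 loci. A further H3K27me3 region of 101952 bp lay at Pax3, a regulator of muscle and neural crest precursors (chromosome 1, 78128969 to 78230920, mm10). Ring1b regions overlapped H2AK119ub in 1227 of 2506 cases (49.0%, 95% interval 47.0 to 50.9) and H3K27me3 in 1314 (52.4%, 50.5 to 54.4). Shifted regions gave means of 1.101% and 1.69%.

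H2AK119ub regions overlapped H3K27me3 in 1576 of 2473 cases (63.7%, 95% interval 61.8 to 65.6) and Ring1b in 1228 (49.7%), but in 43.3% and 28.5% with replicate 2 as the only H2AK119ub list. H3K27me3 regions overlapped H2AK119ub in 48.6% and Ring1b in 42.5% of 2886 cases, but in 27.7% and 23.9% with replicate 1 as the only H3K27me3 list. All 6 ordered pairs exceeded every shift (two-sided permutation test, adjusted p = 0.002, the smallest that 1000 shifts can give). Shifted regions do not stay at promoters, so unrelated lists that both lie there could also exceed the shifts. An expectation matched for promoters was not computed. On the other side, 906 Ring1b regions (36.2%) met no H2AK119ub peak in either replicate and 1001 (39.9%) met no H3K27me3 peak, while 373 and 191 met a peak in 1 replicate. The shares without a peak were 15.9% and 20.8% among peaks with a deposited p of at most 0.001, and 54.7% and 56.6% in the union lists. Of the H3K27me3 regions, 1283 (44.5%) met no Ring1b peak, and with replicate 1 as the only H3K27me3 list 4072 of 6040 (67.4%) did not. The share depended on the lists compared: single Ring1b lists overlapped single H2AK119ub lists in 33.9% to 55.9% and single H3K27me3 lists in 37.4% to 55.6% of peaks, over the 4 replicate combinations of each pair.

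**Figure D1:**
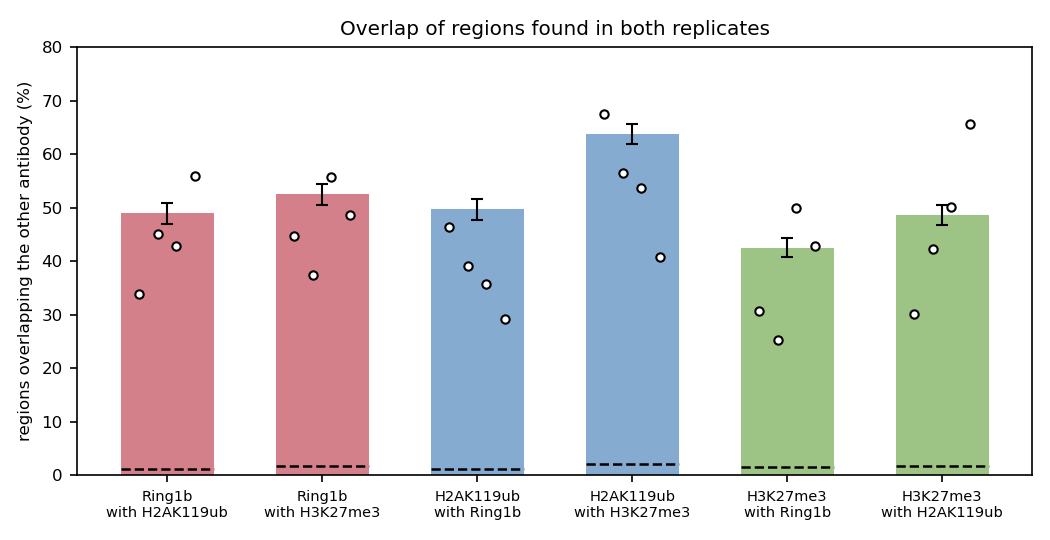
Bars give the percentage of regions of the first antibody, found in both replicates, that overlapped a region of the second by at least 1 bp, with 95% Wilson intervals, and open circles give the 4 combinations of single replicate lists. Dashed lines are means over 1000 shifts, which lay between 1.101% and 2.07%, below bars of 42.5% to 63.7%.

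The second comparison sorted genes by the combination of marks at their promoters. Genes were matched by the names in promoter rows, so peaks of different antibodies or replicates at a gene did not have to overlap. Ring1b lay at 1984 of 21631 protein-coding genes (9.17%), H2AK119ub at 1494 (6.91%) and H3K27me3 at 1918 (8.87%). All 3 were found at 739 genes, which was 37.2% of the Ring1b genes, and Ring1b with no peak of either mark at 608 genes (30.6%). Single lists gave more genes, 3531 with Ring1b in replicate 1 and 2507 with H2AK119ub in replicate 2, and the order of the last counts turned with a single Ring1b list, to 853 with all 3 and 1699 with neither mark in replicate 1, and 767 and 831 in replicate 2. Genes with both marks and no Ring1b peak numbered 191, those with H3K27me3 alone 330 and those with H2AK119ub alone 113. The counts for a mark alone also depended on the lists, at 710 with replicate 1 as the only H3K27me3 list and 422 with replicate 2 as the only H2AK119ub list. Ring1b and H2AK119ub shared 916 genes against 137 for independent sets, Ring1b and H3K27me3 shared 975 against 176, and both marks shared 1072 against 132.

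Genes with all 3 were led by transcription factors of embryonic development. By the averaged rank of the ratio of ChIP to input reads the leading 10 were Tbx2, a T-box factor of heart and limb, Gata2, a factor of blood stem cells, Foxc2, a forkhead factor of lymphatic vessels, Tlx3, which specifies sensory neurons, Hoxd8, Hoxd9 and Hoxd10 under a shared peak, Msx1, a homeobox gene of teeth and limbs, Prdm16, a regulator of brown fat, and Uncx, a homeobox gene of somites. Ring1b reached 8.22 ± 1.18 times input at Tbx2 (SD, n = 2; replicate 1 peak at chromosome 11, 85828704 to 85845159, mm10), 8.91 ± 1.43 at Tlx3, 7.46 ± 0.751 at the shared Hoxd peak and 6.92 ± 1.09 at Msx1. H2AK119ub stood at 2.86 ± 0.236 times its own input over Tbx2 and at 2.60 ± 0.618 over Tlx3. H3K27me3 over Tbx2 averaged 14.3 with an SD of 9.83, and input reads inside autosomal H3K27me3 peaks were 11.8 per kb in replicate 1 and 22.3 per kb in replicate 2.

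Genes with Ring1b and no peak of either mark had a lower median Ring1b ratio, 2.23 (interquartile range 1.93 to 2.83), against 3.20 (2.41 to 4.58) for genes with all 3. The leading 10 were Ciart, a circadian repressor, Anp32b, a nuclear phosphoprotein that chaperones histones, the uncharacterised A430005L14Rik, Tesmin, a gene expressed in testis, Mllt1, a reader of acylated histones in transcription elongation, Usp31, a deubiquitinase, Dcaf10, a substrate receptor of a ubiquitin ligase, Adamts3, a procollagen protease, Ap1s2, a subunit of a clathrin adaptor, and Morc2a, a chromatin ATPase. Ciart carried Ring1b at 7.84 ± 0.991 times input (SD, n = 2; chromosome 3, 95881691 to 95883104, mm10) and Anp32b at 6.42 ± 1.37. At Mllt1 the replicates lay far apart, at 8.23 ± 4.93, over 23 and 7 input reads. Input reads in these 10 peaks were few, from 5 in each replicate at Usp31 to 63 and 59 at Ap1s2, against 400 and 396 at Tbx2. A high rank here can therefore reflect a low input count as well as Ring1b signal. The count of this class depended on the lists: with replicate 1 as the only Ring1b list it was 1699 genes, in the union lists 1917, and among peaks with a deposited p of at most 0.001 it was 108.

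The genes with both marks and no Ring1b peak were led by C1ql2, a synaptic protein, Asic4, an acid-sensing ion channel subunit, Znrf4, a membrane ubiquitin ligase of testis, Adgrb1, an adhesion receptor of brain, Cacna1i, a T-type calcium channel, Rap1gap, which inactivates the GTPase Rap1, Hes3, a repressor in neural progenitors, Kcnc1, a potassium channel of fast-spiking neurons, Fbll1, a fibrillarin relative, and Speg, a kinase of striated muscle. H2AK119ub stood at 3.56 ± 0.205 times input at C1ql2 (SD, n = 2) and at 2.37 ± 0.0265 at Kcnc1. Input reads in the H2AK119ub peaks of these 10 genes ran from 9 at Speg to 67 at Hes3 in replicate 1. In replicate 2 they ran from 27 at Fbll1 to 275 at Hes3. Here too a high rank can reflect a low input count. The class held 191 genes, 305 with replicate 2 as the only Ring1b list, 320 with replicate 2 as the only H2AK119ub list, and 474 in the union lists.

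The third comparison asked which gene groups, drawn up before the data were examined, carried each combination. Regulators of other germ layers and lineages carried them at most of their members. All 3 of Ring1b, H2AK119ub and H3K27me3 lay at 48 of 57 neural regulators (84.2%, against 3.20% of other genes, adjusted exact p = 5.50e-60), 35 of 44 regulators of mesoderm and muscle (79.5%, adjusted exact p = 1.71e-42) and 17 of 21 regulators of endoderm (81.0%, adjusted exact p = 3.33e-21; two-sided Fisher's exact tests, Benjamini-Hochberg over 90 tests). Neural examples were Pax6, a regulator of eye and forebrain, with Ring1b at 5.47 ± 0.677 times input (SD, n = 2), and En1, a midbrain factor, at 6.40 ± 0.865. In the mesoderm group Gsc, a gene of the gastrula organizer, had the highest Ring1b ratio of the genes named here, 10.4 ± 0.766 (chromosome 12, 104469526 to 104480473, mm10), and Gata4, a heart factor, had 6.38 ± 0.788. The muscle factors Myf5, Myf6 and Myog had no promoter peak in any list, and Myod1, the master regulator of muscle, had both marks without Ring1b. Endoderm examples were Foxa1, a pioneer factor of liver and lung, at 8.16 ± 0.749, Pdx1, which specifies pancreas, at 4.77 ± 0.224, and Cdx2, which specifies intestine, at 3.22 ± 0.156.

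Hox genes carried all 3 at 23 of 39 members (59.0%, adjusted exact p = 2.26e-23), but the 30 members with Ring1b, 26 with H2AK119ub and 24 with H3K27me3 shared only 8, 9 and 5 regions, so the test counts linked genes. The Hoxd cluster had all 3 at each of its 9 genes, Hoxa at 5 of 11, Hoxb at 4 of 10 and Hoxc at 5 of 9. Hoxa4, Hoxc4 and Hoxc6 were among the members that no promoter row of any list named. The longest Ring1b region nevertheless ended at 102999128, inside the span of Hoxc6 (102998226 to 103011882, mm10). Hoxb4 had Ring1b at 2.16 ± 0.121 times input (SD, n = 2) with no peak of either mark.

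**Figure D2:**
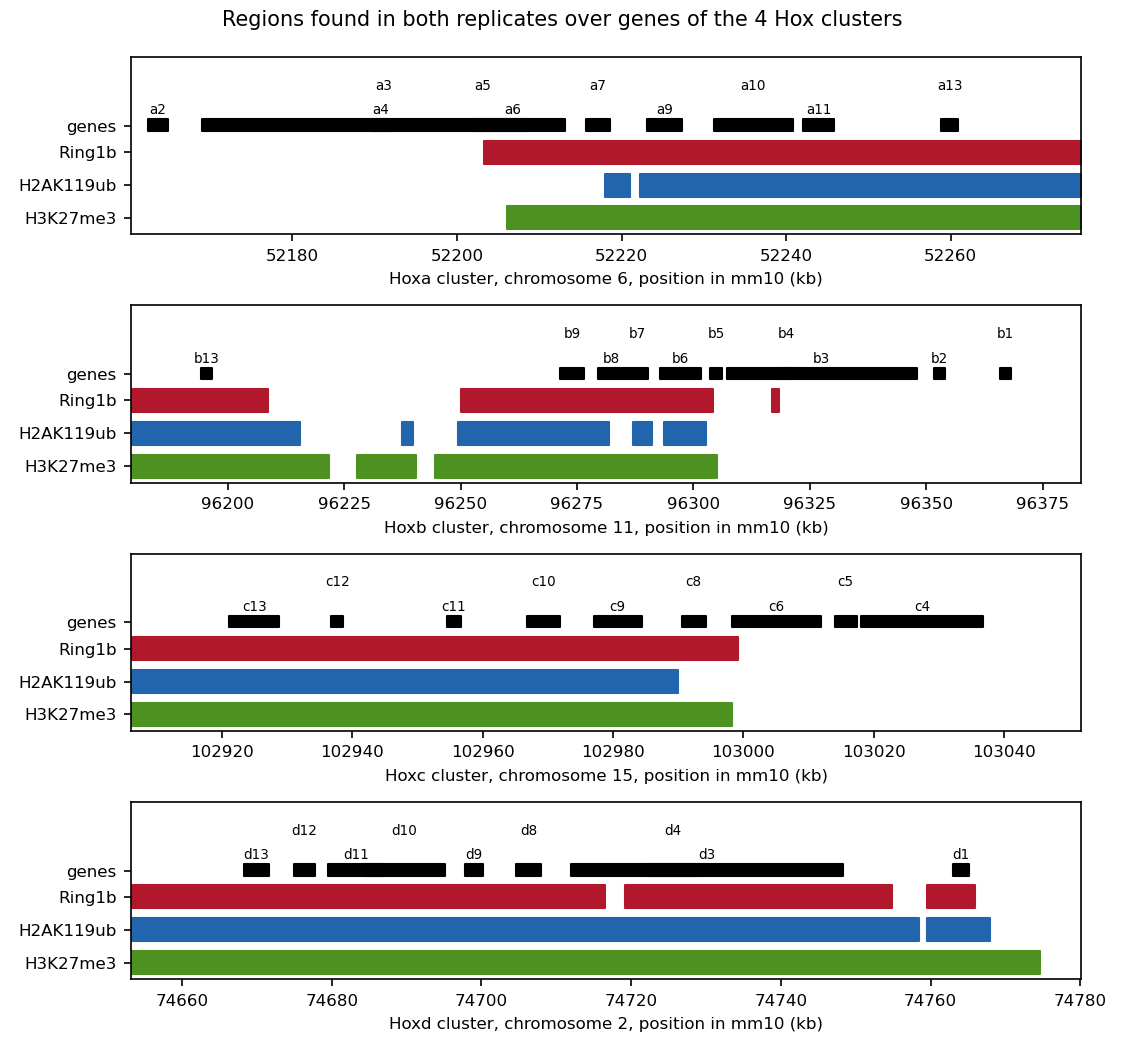
Horizontal bars show regions found in both replicates of Ring1b (red), H2AK119ub (blue) and H3K27me3 (green) over the 4 Hox clusters, with gene spans in black and positions in kb of mm10. Regions covered the side of the clusters with the higher gene numbers and, in Hoxd, all 9 genes. No promoter row named Hoxa4, Hoxc4 or Hoxc6, though a Ring1b region reached into the span of Hoxc6. The Hoxa panel starts at Hoxa2.

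Secreted signals were covered in part. Ring1b lay at 26 of 45 signalling ligands, and all 3 at 16 (35.6%, adjusted exact p = 2.82e-12), including Shh, the hedgehog ligand that drives hair follicle growth (Ring1b 2.54 times input in both replicates), Fgf8, a ligand of limb and brain patterning (3.04 ± 0.604, SD, n = 2), Bmp6 (3.95 ± 1.04) and Gdf7 (3.78 ± 0.0581). Bmp4, Wnt5b, Wnt7a, Wnt7b and Wnt9b had Ring1b and H2AK119ub with no H3K27me3 peak, and Bmp7, a bone morphogenetic protein, had Ring1b alone at 2.102 ± 0.121.

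Genes of Merkel cells, the touch receptors that arise from basal epidermis, had all 3 at 7 of 23 members (30.4%, adjusted exact p = 2.49e-05). These were Atoh1, the factor that starts the lineage, Sox2 and Isl1, which mature it, Gfi1, Insm1, the mechanosensitive channel Piezo2 and the simple keratin Krt8. Ring1b reached 7.65 ± 1.06 times input at Sox2 (SD, n = 2; chromosome 3, 34639651 to 34669074, mm10), 6.42 ± 0.194 at Isl1, 5.04 ± 0.750 at Insm1, 4.37 ± 0.583 at Atoh1 and 2.59 ± 1.12 at Krt8. Krt18, Nefm and Tubb3, a partner keratin of Krt8 and a pair of neuronal cytoskeleton proteins, had both marks without Ring1b, and Krt20 had no promoter peak in any list.

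Hair follicle genes carried Ring1b at 16 of 35 members (45.7%, adjusted exact p = 5.89e-08), H2AK119ub at 11 (adjusted exact p = 4.38e-05), H3K27me3 at 8 (adjusted exact p = 0.0239) and all 3 at 6 (adjusted exact p = 0.00305). The last were Lhx2, a factor of hair follicle stem cells (Ring1b 4.90 ± 0.538, SD, n = 2), Foxc1 (5.05 ± 0.814), Tbx1 (2.74 ± 0.335), Msx1, Nfatc1 and Lgr5, the last a marker of cycling stem cells. Ring1b without either mark was found at Fgfr1, a growth factor receptor (3.50 ± 0.707), Foxp1 (2.19 ± 0.262) and Tcf7l1, a repressor of the Wnt pathway (1.77 ± 0.103). Sox9, a stem cell factor, and Dlx3, a homeobox gene of hair and differentiation, had Ring1b and H2AK119ub without an H3K27me3 peak.

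For genes of the epidermis itself no enrichment was detected in regions of both replicates, though basal genes passed in an alternative given below. Of 29 basal genes 5 had Ring1b (17.2%, adjusted exact p = 0.322) and 0 had all 3. A further 6 had a Ring1b peak in 1 replicate, so 11 of 29 had one in some replicate. In the union lists 3858 of 21631 protein-coding genes (17.8%) had Ring1b, and no test is given for this comparison. Krt5 and Krt14, the paired basal keratins, Trp63, the master regulator of stratified epithelium, and Itga6 and Col17a1, which anchor basal cells, were among 16 members with no promoter peak in any list. The 5 genes with Ring1b in both replicates were Klf5, with neither mark (2.16 ± 0.176 times input, SD, n = 2), and Bnc1, Jag2, Notch1 and Tfap2c, each with an H2AK119ub peak in 1 replicate. Of 35 differentiation genes 5 had Ring1b (adjusted exact p = 0.406), 3 had H3K27me3 and 0 had H2AK119ub in both replicates. Krt10, Ivl and Flg, genes of the suprabasal and cornified layers, had no promoter peak in any list, and Krt1 had only an H2AK119ub peak in 1 replicate. Ring1b with neither mark lay at Lor, the main cornified envelope protein (2.61 ± 0.557), Grhl1, a barrier transcription factor (2.67), and Ovol1, which restrains basal proliferation (2.47 ± 0.324), and Prdm1, a transcriptional repressor, had Ring1b and H3K27me3.

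Adhesion and cytoskeleton genes had Ring1b at 4 of 47 members (8.51%, adjusted exact p = 1): Ocln, a tight junction protein (2.26 ± 0.0638, SD, n = 2), and Rhob, a small GTPase (2.05 ± 0.344), with neither mark, Pkp2, a desmosomal plaque protein, with H3K27me3, and Myh10, a nonmuscle myosin (2.72 ± 0.671), with both. A further 12, such as Cdh1, the E-cadherin gene, had a Ring1b peak in 1 replicate. In the union lists 13 of 47 had Ring1b with neither mark (27.7% against 8.82% of other genes, adjusted exact p = 0.000433), and with replicate 1 as the only Ring1b list 12 did (adjusted exact p = 0.000566).

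Of 7 cell cycle inhibitors 4 had Ring1b (adjusted exact p = 0.00537). Cdkn2a, a classical Polycomb target that halts division, had all 3, with Ring1b at 3.93 ± 0.520 times input (SD, n = 2; chromosome 4, 89269464 to 89311356, mm10), and Cdkn2b lay under the same regions except for H2AK119ub, found in 1 replicate. Cdkn2c, an inhibitor of the same family, had Ring1b alone at 3.28 ± 0.398, and Cdkn1c had Ring1b and H2AK119ub. Of 30 Polycomb subunits 8 had Ring1b (26.7%, adjusted exact p = 0.0118). Cbx8, a reader of H3K27me3, had all 3 (3.70 ± 0.602), while Kdm2b, which brings PRC1 to unmethylated CpG islands (3.58 ± 0.281), and Eed, a core subunit of Polycomb repressive complex 2 (2.05 ± 0.226), had Ring1b with neither mark. Over the 18 lists 0 were enriched among genes with Ring1b and neither mark. This class held 2.81% of protein-coding genes, so few members of most lists were expected in it and a moderate enrichment could be missed. Odds ratios ran from 0, as at the neural regulators, to 5.77 at the cell cycle inhibitors (1 of 7). At an unadjusted p under 0.05 only olfactory receptors differed, and they were depleted. With the union lists 3 were enriched, the adhesion genes above, the cell cycle inhibitors (3 of 7, adjusted exact p = 0.0370) and the Polycomb subunits (10 of 30, adjusted exact p = 0.000443), and replicate 1 as the only Ring1b list also gave these 3. With replicate 1 as the only H2AK119ub list the Polycomb subunits (5 of 30, adjusted exact p = 0.00780) and the basal genes (4 of 29, adjusted exact p = 0.0334) were enriched. H2AK119ub peaks of replicate 2 did not count against an absence there. Of the basal genes with Ring1b, only Klf5 had no H2AK119ub peak in either replicate. The other basal genes counted had one in replicate 2, so they did not lack the mark in both replicates.

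Markers of cells that a sort could carry over were mixed. Of 16 dermal fibroblast genes 5 had H2AK119ub (adjusted exact p = 0.00948) and 5 had H3K27me3 (adjusted exact p = 0.0239), with Pdgfra, a growth factor receptor, under all 3 (Ring1b 4.42 ± 0.313, SD, n = 2) and Col1a1 and Vim under both marks without Ring1b. Of 12 endothelial genes 3 had all 3 (adjusted exact p = 0.0173, but 0.0569 in the union lists): Flt1 and Kdr, receptors for vascular growth factor, and Erg, an endothelial transcription factor. Melanocyte genes had Ring1b at 0 of 10 and H3K27me3 at 2, Sox10 and Kit, and immune genes had Ring1b at 1 of 18 and H3K27me3 at 2 (adjusted exact p = 0.855, 0.367, 1 and 0.888). Ribosomal protein genes, active in all cells, had Ring1b at 4 of 51 (adjusted exact p = 1), among them Rpl12 (2.98 ± 0.552), and H3K27me3 at 0 (adjusted exact p = 0.0475). With replicate 2 as the only Ring1b list 7 of 51 had Ring1b with neither mark (13.7%, adjusted exact p = 0.00846). Olfactory receptors, silent in skin, had Ring1b at 1 of 1106 (adjusted exact p = 1.03e-44) and H3K27me3 at 2 (adjusted exact p = 1.97e-41).

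**Figure D3:**
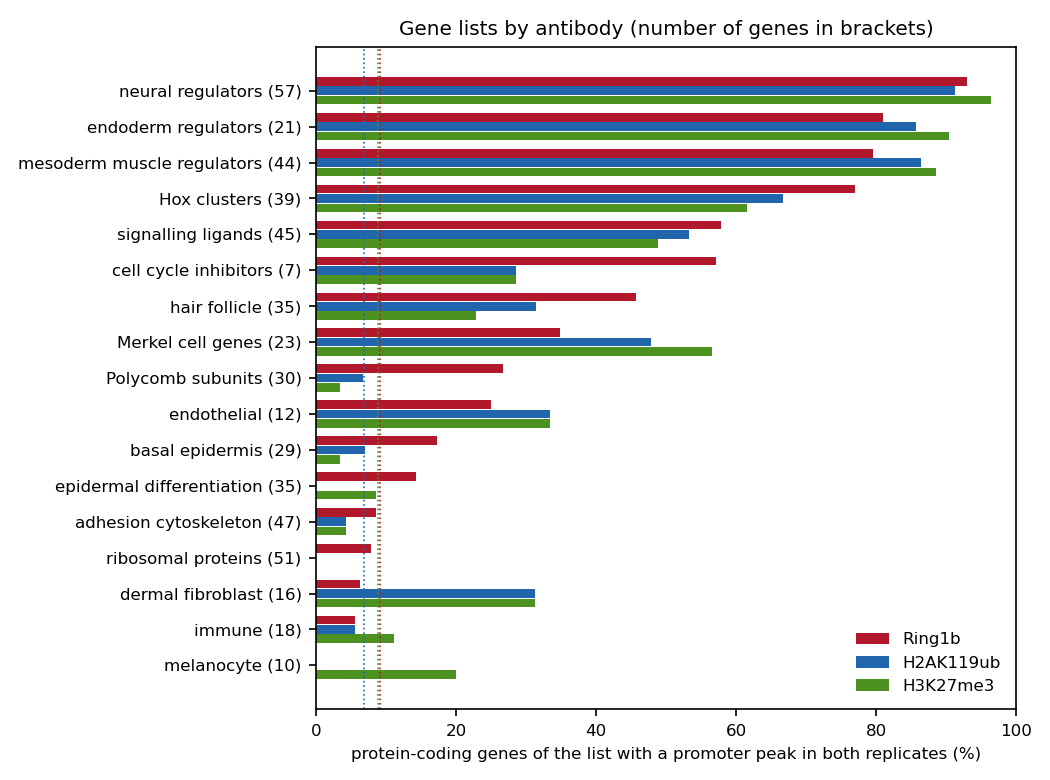
Bars give the percentage of each list's protein-coding genes with a promoter peak in both replicates of Ring1b (red), H2AK119ub (blue) and H3K27me3 (green), with list sizes in brackets. Dotted lines mark the share among genes outside a list, averaged over the plotted lists. They lie close to the shares over all 21631 genes (9.17%, 6.91% and 8.87%). Neural, endoderm and mesoderm regulators stand at 79.5% to 96.5%, and basal and differentiation genes at 0% to 17.2%; olfactory receptors are left out.

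Differences between marks within a list did not pass the threshold. Among hair follicle genes 9 had Ring1b without H3K27me3 and 1 the reverse (exact McNemar p = 0.0215, adjusted p = 0.102). Among Polycomb subunits these numbers were 7 and 0 (exact p = 0.0156, adjusted p = 0.102), and among Hox genes 6 and 0 (exact p = 0.0312, adjusted p = 0.102). Here a gene without a mark is any not found in both replicates, and all 13 comparisons missed the threshold after adjustment. Most of these comparisons rested on only 6 or 7 genes that differed. Splits of 6 and 0 or 7 and 0 are the most one-sided possible at those numbers, and they still missed it. The tests could therefore hardly detect a difference, and none is excluded.

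The fourth comparison related the strength of Ring1b to the marks beside it. Ring1b regions with H2AK119ub had a median ratio of 2.86, against 2.23 where no H2AK119ub peak was found. On the log2 scale the medians were 1.52 (1227 regions) and 1.16 (906 regions), a difference of 0.36. Regions with H3K27me3 had a median log2 ratio of 1.45 (1314 regions) and those without 1.21 (1001 regions), a difference of 0.24. Both differences gave p = 1e-05 in two-sided permutation tests, the smallest that 100000 resamples can give. Marked Ring1b regions were also longer, with medians of 3574 bp against 1440 bp for H2AK119ub and 3454 bp against 1472 bp for H3K27me3. Among peaks with a deposited p of at most 0.001 the difference for H3K27me3 was 0.03 (permutation p = 0.425) and that for H2AK119ub was 0.16 (permutation p = 0.0112). That limit also raised the median ratios being compared, more so in regions without the mark.

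**Figure D4:**
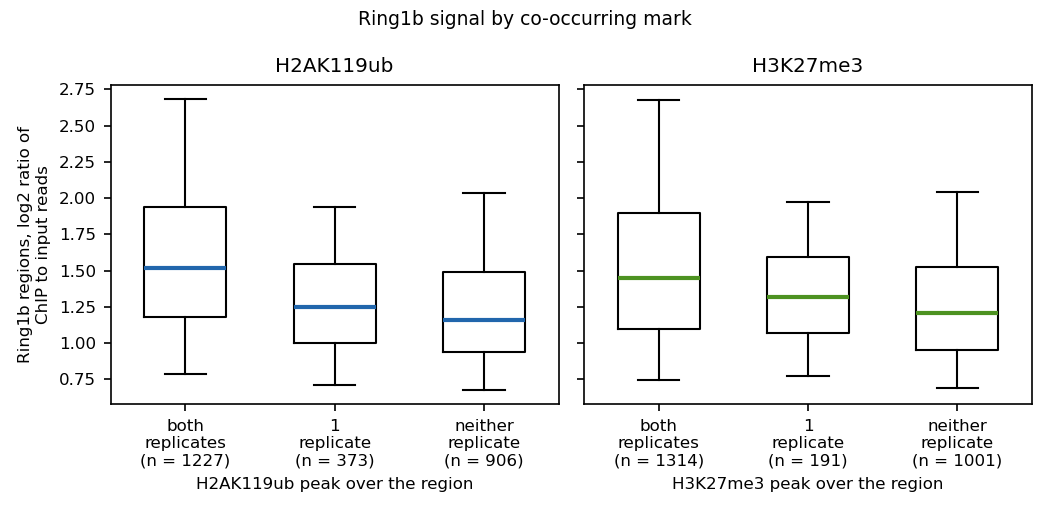
Boxes show the log2 ratio of ChIP to input reads in Ring1b regions, split by whether an H2AK119ub (left) or H3K27me3 (right) peak was found in both replicates, in 1 or in neither, with the median as a coloured line, the interquartile range as a box and whiskers from the 5th to the 95th percentile. Medians were 1.52 and 1.45 with the mark in both replicates, above 1.16 and 1.21 with it in neither.

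Ring1b lay mostly at promoters. By the authors' location class 1977 of 2506 Ring1b regions held a promoter peak (78.9%, 95% interval 77.2 to 80.4), against 1957 of 2886 H3K27me3 regions (67.8%, 66.1 to 69.5) and 1576 of 2473 H2AK119ub regions (63.7%, 61.8 to 65.6). Within 2000 bp of an end of a protein-coding gene lay 75.8%, 67.1% and 64.3% of them, and 10.3%, 16.1% and 13.4% after shifting (two-sided permutation p = 0.002 for each, the smallest the shifts can give). Gene bodies held 8.94% of Ring1b peaks and 24.3% of H2AK119ub peaks in replicate 1 (9.71% and 23.6% in replicate 2).

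Chromosome X carried fewer regions than the autosomes for all 3 antibodies, given here as values without a test. Ring1b had 0.191 regions per Mb on chromosome X against 0.997 on the autosomes, whose lowest was 0.671. H2AK119ub had 0.133 against 0.988 and H3K27me3 0.423 against 1.13. Ring1b lay at 2.38% of the protein-coding genes of chromosome X and 9.49% of autosomal ones, and H3K27me3 at 5.49% and 9.02%. Input reads per kb inside peaks were also lower on chromosome X, at 0.753 to 0.806 of the autosomal value over the 6 lists. The X-linked genes with all 3 included Esx1, a homeobox gene of placenta, with Ring1b at 4.65 times input, and Pcdh19, a protocadherin of brain, at 3.34. The sex of the pups is not given in the labels.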

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

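The test of random background calls was set before its result was seen, and the comparison by ratio was chosen only after it. H3K27me3 peaks found in replicate 1 and not in replicate 2 were left out of the regions found in both replicates, yet 252 of 3127 (8.06%) overlapped H2AK119ub regions, and this signal outside the main measurement is why they are listed here. Random background calls would overlap H2AK119ub regions about as often as shifted peaks, but the share was 7.51 times the shifted mean of 1.07% (two-sided permutation p = 0.002, the smallest the shifts can give), and Ring1b regions were met by 6.46% against 0.787%. Background calls placed at random along the chromosomes therefore do not account for all of these peaks. Background that gathers near genes was not tested and stays open, since H2AK119ub regions also lie there (64.3% near a gene end against 13.4% after shifting). Background calls could account for many of the peaks, since peaks shared with replicate 2 overlapped H2AK119ub in 48.7% and Ring1b in 42.7% of cases. Lower enrichment in replicate 2 cannot be told apart from other explanations. The share of replicate 1 peaks found again in replicate 2 rose by 87.3 percentage points, from 3.71% in the lowest quartile of the replicate 1 ratio to 91.0% in the highest, but background calls would also have low ratios and be found again less often. In shared regions replicate 1 held 144 ChIP and 11.4 input reads per kb and replicate 2 held 116 and 22.2, and without library totals a weaker pull-down and a different input depth remain open; no biological explanation was tested.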

How the results depend on the processing

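The limits on the deposited p and the other ways of naming genes were added after the data had been seen; the rest had been set beforehand, except that CpG-rich promoters, start windows of 1000 and 5000 bp, the most upstream start and the q threshold were not run. Shares of regions overlapping another antibody or at promoters (9 results) stayed on the same side of the threshold under all 81 alternatives, but each gave p = 0.002, the smallest that the shifts can give, so the permutation p could not show a weaker result and the shares are the better guide. Ring1b overlapped H2AK119ub in 34.3% to 61.7% and H3K27me3 in 37.8% to 72.5%, H2AK119ub overlapped Ring1b in 28.5% to 59.6% and H3K27me3 in 43.3% to 80.1%, and H3K27me3 overlapped Ring1b in 15.2% to 52.6% and H2AK119ub in 27.7% to 67.2%. The lowest values for H3K27me3 came from an overlap covering at least 50% of the region (Ring1b) and from leaving out H3K27me3 replicate 2 (H2AK119ub). Promoter shares were 76.2% to 79.9% for Ring1b, 42.6% to 74.6% for H2AK119ub and 46.1% to 68.0% for H3K27me3. Of 66 alternatives for gene counts 18 moved the count by over 1.5 times. In the union lists Ring1b genes numbered 3858, H2AK119ub genes 2619, genes with all 3 1258, with Ring1b and neither mark 1917, and with both marks and no Ring1b 474, and 3 lists were enriched among genes with Ring1b and neither mark. With p of at most 0.001 these counts were 846, 790, 402, 108 and 81, and with p of at most 0.05 Ring1b with neither mark fell to 355. Leaving out each replicate gave 2320 to 3531 Ring1b genes (highest without Ring1b replicate 2), 1692 to 2507 H2AK119ub genes (highest without H2AK119ub replicate 1), 608 to 1699 with Ring1b and neither mark (highest without Ring1b replicate 2), 191 to 320 with both marks and no Ring1b (highest without H2AK119ub replicate 1), and 0 to 3 lists enriched with Ring1b and neither mark. These moves follow from admitting peaks of a single list or removing peaks. With the replicate number as a replicate block, means over same-numbered lists were 1411.5 genes with Ring1b and neither mark and 400 with both marks and no Ring1b, against 1418.67 and 421.5 for crossed lists, so the numbers were treated as names. The other gene counts and the overlap shares kept their call under this block; gene list counts, promoter shares and Ring1b differences were not run under it. The Ring1b difference between regions with and without H3K27me3 was 0.0308 on the log2 scale with p of at most 0.001 (permutation p = 0.425). This limit also selected on the ratio compared. Median log2 ratios rose from 1.21 to 1.75 without the mark and from 1.45 to 1.78 with it. Whether this selection alone closed the gap was not tested. The other 11 alternatives for such differences kept their call. Lists enriched among genes with all 3 numbered 7 to 9: endothelial genes lost the call in the union lists (adjusted exact p = 0.0569), and cell cycle inhibitors gained it with gene spans in place of promoters (adjusted exact p = 0.00673). Depth limits calls of absence, since the lowest ChIP count of a peak was 20 reads and library totals are not given.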

Other observations

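The tests of weak Ring1b signal and of active promoters, the split of the Hox genes and the comparison of X-linked with autosomal H3K27me3 genes were chosen only after results had been seen. Along the Hox clusters, which are expressed in order of their paralogue numbers, Polycomb marks sat towards the higher numbers. Ring1b lay at 21 of 21 genes of groups 7 to 13 and at 9 of 18 genes of groups 1 to 6, H2AK119ub at 21 and 5, H3K27me3 at 19 and 5, and all 3 at 19 and 4. The covered genes share 8 Ring1b, 9 H2AK119ub and 5 H3K27me3 regions, so no p is given for this split.

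On chromosome X, H3K27me3 stood more often by itself. Of 53 X-linked genes with H3K27me3, 25 (47.2%) had no peak of Ring1b or H2AK119ub in either replicate, against 305 of 1865 autosomal genes (16.4%; two-sided Fisher's exact test, p = 2.87e-07, 1 test, genes not independent). Input reads per kb inside peaks on chromosome X were 0.753 to 0.806 of the autosomal value. Median ChIP reads per peak were 60 to 109 for Ring1b and H2AK119ub and 418.5 and 434 for H3K27me3. Lower coverage could therefore remove Ring1b and H2AK119ub calls first, and this was not tested. Examples were Htr2c, a serotonin receptor, Nr0b1, a nuclear receptor of adrenal and gonad, and Il1rapl1, a synaptic receptor, with H3K27me3 at 8.53, 8.70 and 7.56 times input. H3K27me3 peaks found in replicate 1 and not in replicate 2 also lay more often on chromosome X, 173 of 3127 (5.53%) against 74 of 2913 shared peaks (2.54%; two-sided Fisher's exact test, p = 3.37e-09), and fewer of them lay at promoters (25.8% against 67.9%) and more between genes (24.4% against 10.99%). For Ring1b the shares on chromosome X ran the other way, 0.780% of peaks in replicate 1 alone and 1.34% of shared peaks, without a test. For H2AK119ub they ran as for H3K27me3, 1.75% (12 of 687) and 1.06% (33 of 3113), also without a test.

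Ring1b regions with neither mark in any replicate numbered 718 of 2506 (28.7%). With weak Ring1b signal as the only cause, under 5% of the decile with the highest Ring1b ratio would lack both marks, but 9.16% of it did (23 of 251, 95% interval 6.18 to 13.4). This ratio is also high where input reads are few, and in the decile with the greatest peak height only 1.195% did (3 of 251, 95% interval 0.407 to 3.45), so the measures disagree and weak signal stays open. The share was 41.8% in the decile with the lowest ratio, and with p of at most 0.001 regions without H2AK119ub fell from 36.2% to 15.9% and those without H3K27me3 from 39.9% to 20.8%. Pull-down at any highly active promoter would place Ring1b by itself at over 20% of ribosomal protein genes, but it did so at 5.88% (3 of 51, 95% interval 2.02 to 15.9), and 42 of 51 had no Ring1b peak in either replicate. With replicate 2 as the only Ring1b list the share was 13.7% (7 of 51, 95% interval 6.81 to 25.7, adjusted exact p = 0.00846), an interval that holds the bound, so such pull-down stays open. The shortest length admitted to the H3K27me3 lists bears on H3K27me3 peaks alone, since H2AK119ub and Ring1b peaks were listed from 500 bp, so it leaves the missing H2AK119ub peaks unexplained. For the missing H3K27me3 peaks it cannot be told apart from a real absence: among Ring1b regions of at least that length 10.7% (151 of 1412, 95% interval 9.19 to 12.4) lacked both marks, an interval that holds the bound of 10% set beforehand, against 51.8% of shorter ones. No biological explanation was tested.

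Fewer regions of all 3 antibodies lay on chromosome X. Lower coverage of that chromosome is a candidate explanation, since a single X in male cells lowers it, and the sex of the pups is not given in the labels. When peak heights were scaled to the input coverage of chromosome X, 35.5% of autosomal Ring1b regions (878 of 2473) no longer had a peak above the lowest listed height in both replicates, between the bounds of 30% and 50% set beforehand, so the test does not decide. The loss under this scaling was smaller than the deficit (0.191 against 0.997 Ring1b regions per Mb), so on this reckoning coverage may account for a part only. Gene content was not tested.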
